A study of Mus musculus with 2 samples.

How the data were processed

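Gene expression was measured on 2 microarrays. The first held RNA of wild-type innate lymphoid cell (ILC) progenitors and the second RNA of ILC progenitors labelled as coming from mice with a Yeats4 deletion, whose littermates were the wild type per the design text. Per the labels' protocols, the cells were sorted by flow cytometry as lineage-negative cells that carry CD127 and the integrin α4β7, with intermediate c-Kit and Sca-1. Total RNA was taken with Trizol, and biotin-labelled cDNA was hybridised to Affymetrix arrays. Each genotype has 1 array, and nothing in the labels says how many mice contributed to it.

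The deposited table holds log2 expression values, 1 per probe set and array, which per the submitters' processing notes the authors made with Affymetrix Power Tools and RMA. RMA corrects the background, applies quantile normalization to the arrays and summarises probes into probe sets on the log2 scale. Differences were therefore taken between arrays whose overall distributions had been brought together before probes were summarised, and a change of total RNA per cell would not be visible. The distributions of the probe set values were still not identical, with medians of 2.91 on the wild-type array and 2.87 on the other. Tool versions, the genome build and scanner intensities are not given in the sources used here. The design text names a Mouse Gene 2.0 array, while the probe set names match the annotation of another Affymetrix mouse design. The array type is therefore not settled, and the gene names rest on that annotation. No genome coordinates are printed because no build is named.

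The table lists 29129 probe sets. Of these, 19572 have 1 gene symbol in the platform annotation and none has several. They give 19505 genes, and all of their gene identifiers were found in the reference gene table (GRCm38.p6), which was used for names only. A further 2615 transcript probe sets have no name here. There are also 5222 negative control probe sets, 1324 positive control probe sets and 441 other control or unmapped probe sets, and 45 of the 441 have a gene symbol and are counted among the named ones too. For the 55 genes with several probe sets, the probe set of highest mean was used.

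Genes entered the comparison when the mean of the 2 arrays was at or above the median of all probe sets (2.88 on the log2 scale), which kept 10881 genes. Values were used as deposited, with no further centring. The difference is always the array labelled knockout minus the wild-type array. With 1 array per genotype there is no replicate error and no test, and no p-value is given. As a description of the scatter between these arrays, each difference is set beside the spread (scaled median absolute deviation) of the 500 genes nearest in mean level. The 95th percentile of the negative controls was 4.80 on the wild-type array and 4.73 on the other, and a gene under both is called near background. For a gene under 4.80 on 1 array only, a fold is given as a lower limit, against that level, while log2 differences are given as measured. Such a limit takes the other array's reading as exact. It holds no replicate error and can be smaller than the local spread. The number of arrays limits the precision.

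Before the data were examined, 30 gene lists, the alternatives and the rule for naming genes were fixed. The rule names the 12 largest differences in each direction past the filter and of at least 2-fold, leaving out predicted and non-coding names, olfactory and vomeronasal receptors and antigen receptor segments. It also names Yeats4 and Lmo4, all members of the lists of early ILC commitment regulators and of sort gate genes, and in each other list the 3 members with the largest difference and any member changed 2-fold, up to 6. Other members are named below as examples chosen after their values were seen. For each list the median difference of the members past the filter was computed with an order-statistic binomial interval over members (95%). That interval covers the scatter among genes, not between mice. Below 6 members the range is given instead. The percentile of the median among 10000 random lists of the same size, matched on mean level in 20 bins, describes these 2 arrays only. List members not found in the annotation, such as Tcf7, Gata3, Ly6a, Lck and Xist, were not analysed here. The list of antigen receptor segments was void because its pattern found only Tradd, which is no such segment, and the sex-linked list is given gene by gene.

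The alternatives were no level filter, a filter at the 75th percentile (4.84), centring on the median, a loess correction on level (span 0.3), quantile normalization of the table, the mean of a gene's probe sets, a 1.5-fold threshold and a threshold of 3 local spreads. A filter at the 95th percentile of the negative controls' means (4.75), and values under 4.80 raised to it, were added after seeing the files. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The procedure was tested on simulated data. With noise equal to the local spread, 98.0% of genes with a simulated log2 change of -2 and 92.0% of those with -1.5 passed the 2-fold threshold, and so did 188 of 10681 unchanged genes. Of 400 lists of 14 random genes, 8 fell outside the central 95%, against 397 of 400 lists shifted by -0.5.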

Results

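The series compared sorted wild-type ILC progenitors with progenitors labelled as deficient in Yeats4. Yeats4 encodes a YEATS domain protein that reads acetylated histones and is a subunit of the SRCAP and Tip60 chromatin complexes. ILC progenitors are the bone marrow cells that give rise to helper innate lymphoid cells, and the α4β7-positive fraction is an early stage. The comparison addresses which genes depend on Yeats4 at this stage. Each genotype had 1 array, so every difference below is between these arrays and has no replicate check. The arrays correlated with r = 0.965 across the 10881 genes past the level filter, which are not independent replicates. Over all probe sets the median was 2.91 on the wild-type array and 2.87 on the other. The median difference of the genes past the filter was 0.08 on the log2 scale. It varied with level, from -0.04 at mean levels between 2.88 and 4 to 0.17 between 6 and 7.

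Yeats4 itself did not differ between the arrays by more than genes of like level. The probe set of Yeats4 (Entrez gene 64050) read 5.96 on the wild-type array and 5.90 on the array labelled knockout, a difference of -0.06 against a local spread of 0.34. It was number 142 from the lowest among the 500 genes nearest in level. Where its probes lie relative to the deleted part of the gene is not known here, so the transcript level does not check the label, and the second array is called the array labelled knockout throughout. The other YEATS domain genes Mllt1 (0.51, near background) and Yeats2 (0.07) had a list median of 0.29 (range 0.07 to 0.51, percentile 77.0). The 19 measured genes of SRCAP and Tip60 subunits and H2A.Z had a median of 0.15 (interval -0.05 to 0.31, percentile 60.3) and none differed 2-fold. Those that differed most were Actr6 (0.55, near background on both arrays), Epc2 (0.40, under the negative control level on the wild-type array) and Ing3 (0.33). The chromosomal neighbours of Yeats4 had a median of -0.03 (interval -0.19 to 0.41, percentile 7.57), with Nup107 at 0.44, Cct2 at 0.41 and Lyz2 at -0.26. Among neighbours under the level filter and near background, Cpm was at -1.49 and Lrrc10 at -0.73.

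Lmo4, a LIM domain transcriptional cofactor, showed the largest difference relative to the local spread among all genes past the filter. The probe set of Lmo4 (Entrez gene 16911) read 11.47 on the wild-type array and 9.01 on the array labelled knockout, which is 5.50-fold lower (-2.46 log2, local spread 0.17). No other of the 500 genes nearest in level was as low. Among all genes past the filter Cd3d and Cd8b1 had a lower measured difference, but both were under the negative control level on the array labelled knockout, so their order against Lmo4 is not settled. A published study of Yeats4 in ILC progenitors names Lmo4 as a gene that Yeats4 activates, and these arrays may be among its data, so the value is not independent evidence. The T cell list was also lower on this array (median -1.06). The LIM domain relatives and partners of Lmo4 did not differ alike. The 8 past the filter had a median of 0.05 (interval -0.26 to 0.48, percentile 25.9), which was -0.09 after the loess correction, and Ssbp2 (0.48), Lyl1 (0.41) and Tal1 (-0.26) differed most.

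In all, 170 genes were at least 2-fold higher and 85 at least 2-fold lower on the array labelled knockout, 1.56% and 0.781% of the genes past the filter. Of the 12 genes with the lowest differences, 6 belong to the T cell list. They were the CD3 chains Cd3d (-2.92), Cd3e (-2.10) and Cd3g (-1.63), the CD8 chains Cd8b1 (-2.58) and Cd8a (-2.44), and Themis (-1.76). The others besides Lmo4 were Thy1 (-1.66), the chemokine Ccl5 (-1.78), the eosinophil ribonuclease Ear6 (-1.78), the lipoxygenase Alox15 (-1.68) and Hjv (-1.64). Of the 12, Themis and Hjv were near background on both arrays. The 12 genes with the highest differences lay at low levels, with means between 3.16 and 4.50. They were led by the Y-linked translation factor Eif2s3y (1.78), the centriolar gene Poc1a (1.71) and the macrophage gene Cd5l (1.59). The others were Igfbp5 (1.56), Akap8l (1.56), Tspan4 (1.55), Mtfr1 (1.55), Uty (1.54), Slco4a1 (1.52), Dmkn (1.503), Tmem60 (1.49) and Rhoj (1.48). All 12 were under the negative control level on the wild-type array, and 6 of them were near background on both arrays. Of the rest, Poc1a was at least 1.42-fold, Dmkn 1.37-fold, Mtfr1 1.36-fold and Eif2s3y 1.30-fold higher. Rhoj and Tspan4 were at least 1.18-fold and 1.15-fold higher. Both arrays were near background for 88 of the 170 higher genes and 39 of the 85 lower genes. At mean levels between 2.88 and 4, 2.5% of genes were at least 2-fold higher and 1.2% lower. Control probe sets passed 2-fold more often there, with 5.3% and 8.5% of negative controls and 17.1% and 3.2% of positive controls. At mean levels of 8 or more no control of either kind passed 2-fold, against 0.2% and 0.9% of genes. In the simulation 188 of 10681 unchanged genes passed 2-fold, both directions together. Its noise was set to the spread between these same arrays, which holds any real difference too. It therefore does not give the share of false calls. With a filter at the 75th percentile of level, 35 genes were higher and 25 lower, and with values raised to the negative control level 19 were higher and 23 lower.

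**Figure D1:**
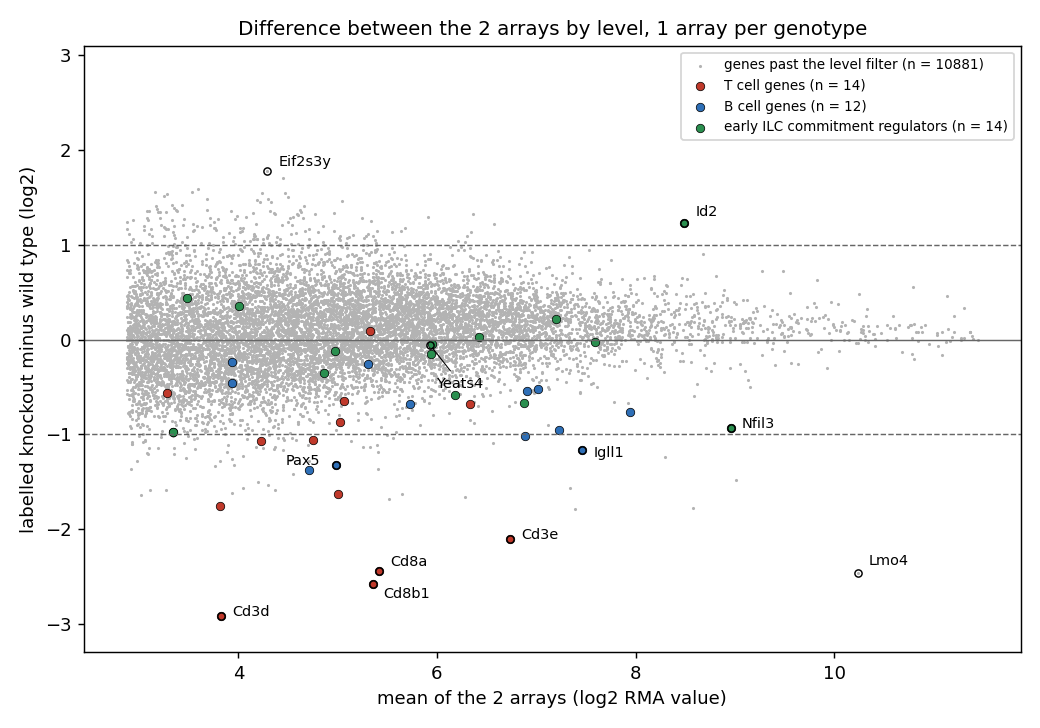
Difference between the array labelled knockout and the wild-type array (log2, vertical axis) against the mean of both (log2 RMA value, horizontal axis) for the 10881 genes past the level filter. Each point is 1 gene, dashed lines mark 2-fold, colours mark 3 of the gene lists, and Lmo4 (-2.46) stands apart at high level while Yeats4 (-0.06) lies among genes of like level.

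The early regulators of ILC commitment did not move as a block. Nfil3, which acts at the start of ILC specification, was 1.91-fold lower (-0.93, local spread 0.17), Ets1 1.59-fold lower (-0.67, spread 0.26) and Tox 1.49-fold lower (-0.58, spread 0.30). Id2, the repressor of E proteins that marks committed ILC progenitors, was 2.35-fold higher (1.23, spread 0.17). Each of these 4 lay among the lowest or highest 1% of the genes nearest in level. Zbtb16, which encodes PLZF, was at -0.35, under the negative control level on the array labelled knockout, and Bcl11b, near background, at -0.98. T cells also express Bcl11b, Ets1 and Tox, and the T cell list had a median of -1.06. Other blood cells express Id2 too, and a macrophage list, written after some of its genes were seen, had a median of 0.79. Little difference was seen for Notch1 (-0.15), Sox4 (-0.12), Notch2 (-0.05), Runx3 (-0.03) and Cbfb (0.03). Runx1 was at 0.22 and Maf, near background, at 0.35. Rora, near background and with 3 probe sets, was at 0.44 on the brightest and at -0.25 over their mean. Of the 14 members, 9 were below 0, and only Id2 passed 2-fold. The list median was -0.08 (interval -0.67 to 0.35) against 0.11 for matched random lists, at percentile 2.48, just inside the lowest 2.5%.

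**Figure D2:**
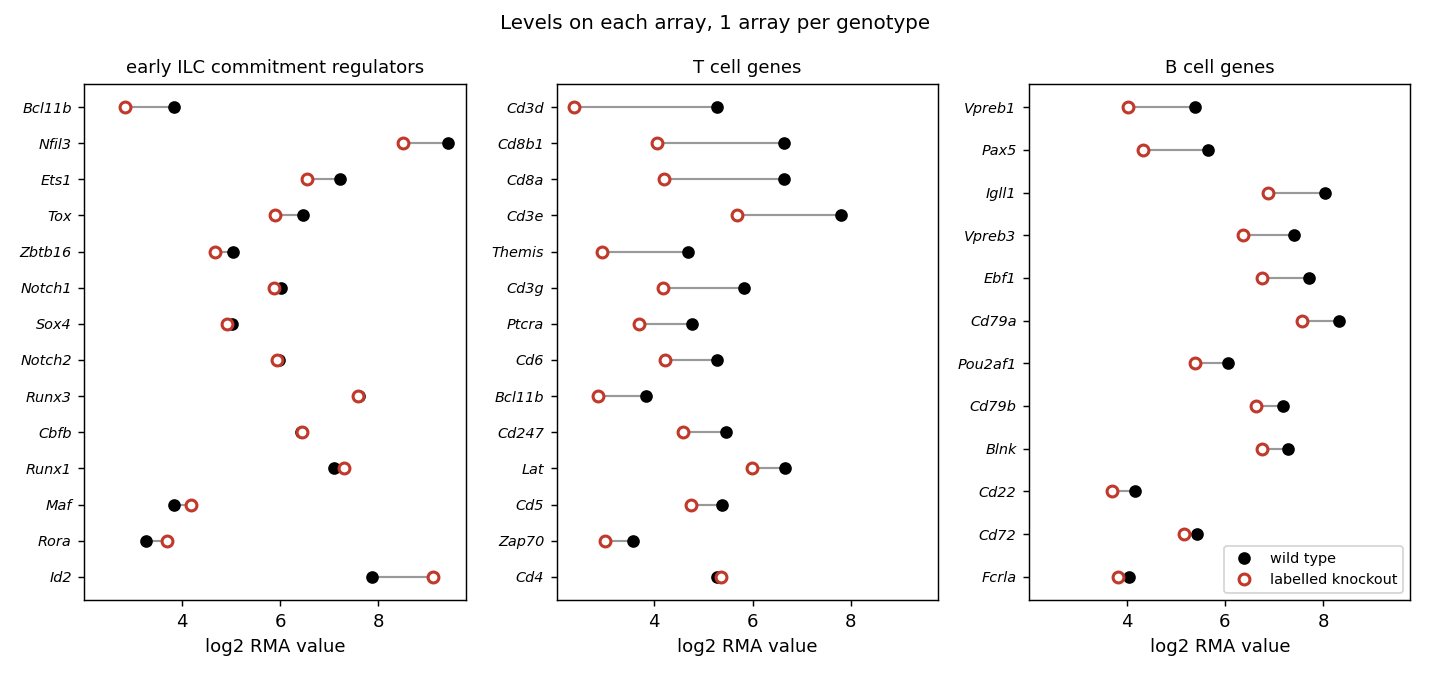
Levels on each array (log2 RMA value, horizontal axis) for the members past the filter of 3 gene lists, with filled points for the wild-type array and open points for the array labelled knockout. In the T cell list 13 of 14 genes lie lower on the array labelled knockout, in the B cell list all 12, and among the early ILC regulators Nfil3 lies lower and Id2 higher.

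Among the genes of the sort gate, Il7r, which encodes CD127, was 1.62-fold lower (-0.70) and Kit 1.57-fold higher (0.65). The integrin genes Itgb7 (-0.14) and Itga4 (0.00) differed little. The list median was -0.07 (range -0.70 to 0.65, percentile 6.32), and the sort selects on these proteins. Of 9 other receptors of ILC progenitors 6 were below 0, while Flt3 (0.46), Pdcd1 (0.08, near background) and Ccr9 (0.00) were not. Their median was -0.63 (interval -1.09 to 0.08), below all 10000 matched random lists, with 2 members at least 2-fold lower and none 2-fold higher. With values raised to the negative control level the percentile was 37.1. The members 2-fold lower were Thy1 (-1.66) and Il2rb, the IL-2 and IL-15 receptor chain (-1.09); Cxcr6, near background, was at -0.89. T cells and NK cells express Thy1 and Il2rb too, and the T cell list was lower on the same array (median -1.06). Components of common gamma chain signalling and survival had a median of -0.12 (interval -0.47 to 0.06, percentile 4.58, and 2.36 after the loess correction), with Socs3 at -0.56 and, near background, Socs1 at -0.47 and Socs2 at -0.23.

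Among the lists of mature ILC subsets, that of NK cells and ILC1 lay outside the central 95% of random lists. NK and ILC1 genes had a median of -0.40 (interval -1.06 to 0.20), and 4 of 10000 random lists were as low, but 6 of its 12 members were near background on both arrays and the percentile was 49.5 with values raised to the negative control level. Ccl5 (-1.78) and Il2rb (-1.09) were at least 2-fold lower and no member was 2-fold higher. Eomes, the T-box factor of NK cells, was under the negative control level on the array labelled knockout and at least 1.24-fold lower (-1.06 as measured). On the log2 scale that limit (-0.31) was smaller in size than the local spread (0.45). Nkg7 (0.53) and Ncr1 (0.30, near background) lay above 0. T cells express Ccl5 and Il2rb as well. ILC3 and lymphoid tissue inducer genes had a median of -0.34 (range -0.54 to 0.73, percentile 5.04), with Il1r1 at 0.73 and Lta (-0.54) and Il17a (-0.53) near background. The direction was not stable, since the median was 0.20 (percentile 63.1) with the negative control filter and 0.0000 (percentile 49.3) with values raised to the negative control level, against -0.33 (percentile 1.49) with no level filter. Only 4 ILC2 genes passed the level filter. Their median was -0.01 (range -0.34 to 0.44, percentile 50.5), with Il17rb at -0.13 and, near background, Il13 at -0.34 and Rora at 0.44. The difference between subsets was not tested.

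T cell and B cell genes were the lowest of the fixed lists, although the sort excluded lineage-positive cells. In the T cell list 13 of 14 genes were lower as measured, with a median of -1.06 (interval -2.44 to -0.64), below all 10000 random lists. As measured 8 were at least 2-fold lower, but this held for only 4 with values raised to the negative control level, namely Cd3e, Cd8b1, Cd8a and Cd3g. Cd3e was 4.30-fold lower. Cd8b1, Cd8a, Cd3g and Cd3d were under that level on the array labelled knockout and at least 3.57-fold, 3.57-fold, 2.02-fold and 1.40-fold lower, whereas Cd4 was at 0.09. With raised values the list median was -0.53 (interval -1.83 to 0.00), still below all random lists. In the B cell list all 12 genes were lower as measured, with a median of -0.72 (interval -1.16 to -0.46), also below all random lists. The surrogate light chain gene Igll1 (-1.16) and Vpreb3 (-1.02) were at least 2-fold lower. The surrogate light chain gene Vpreb1 (-1.37 as measured) and Pax5, the B lineage commitment factor (-1.32), were under the negative control level on the array labelled knockout and at least 1.51-fold and 1.79-fold lower. Ebf1 (-0.95) and Cd79a (-0.76) were lower as well. Notch target genes had a median of -0.61 (range -1.07 to -0.34), and 33 of 10000 random lists were as low. All 5 members past the filter were lower, namely Ptcra (-1.07), which is also a T cell gene, Hey1 (-0.75), Heyl (-0.61), Hes1 (-0.60) and Dtx1 (-0.34). Of these, 4 were near background on both arrays. The remaining member, Hes1, was under the negative control level on the array labelled knockout and at least 1.04-fold lower. With values raised to the negative control level the list lay inside the central 95%. Genes of common lymphoid progenitors had a median of -0.07 (interval -0.31 to 0.39, percentile 2.04) with no 2-fold difference. Flt3 was at 0.46, Cd34 at 0.39 and Lax1 at -0.32.

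**Figure D3:**
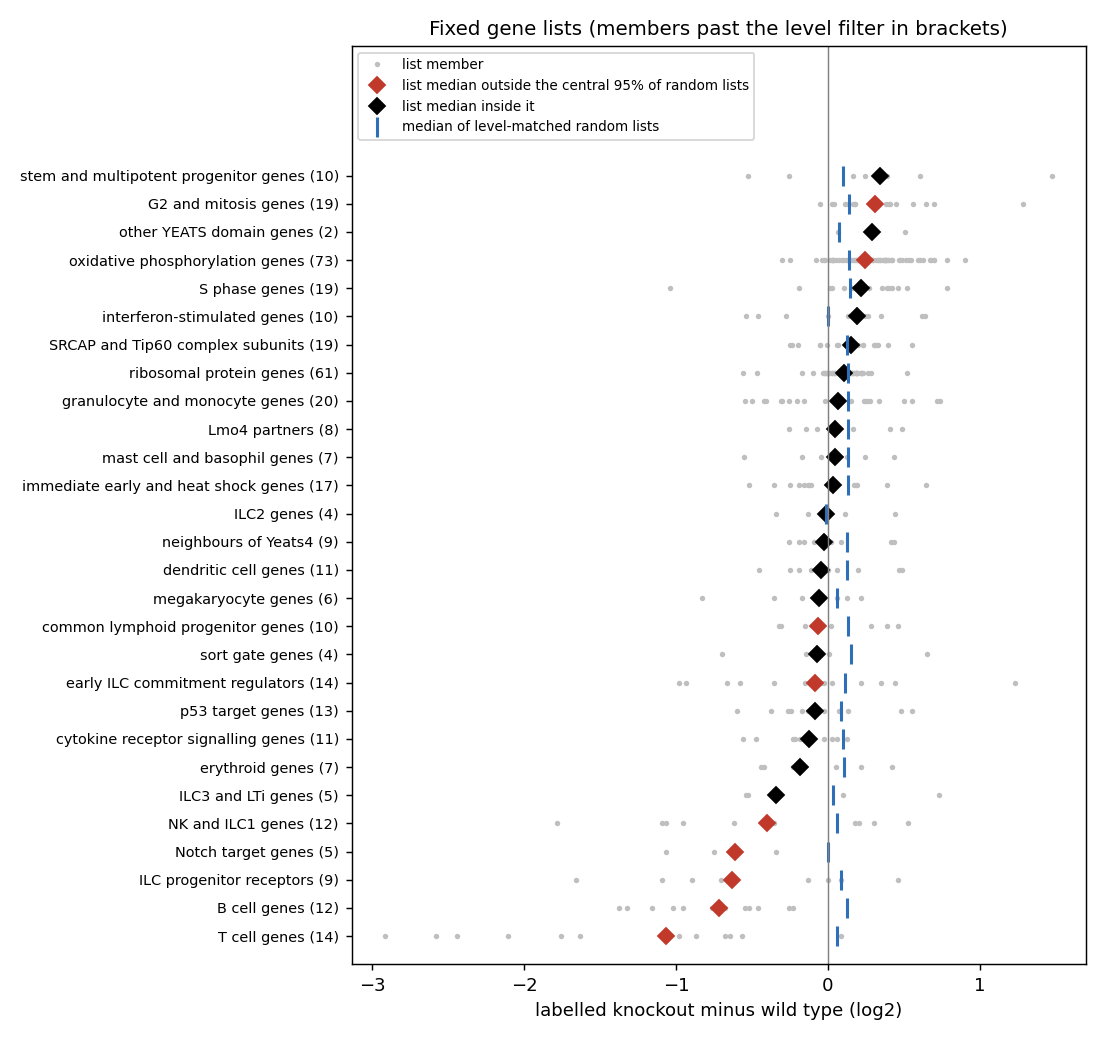
Difference between the array labelled knockout and the wild-type array (log2, horizontal axis) for the 28 fixed gene lists with a median. Grey points are list members past the filter, diamonds are list medians and blue ticks the medians of level-matched random lists; the T cell list (-1.06) and the B cell list (-0.72) are the lowest.

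The fixed lists of other blood lineages lay inside the central 95% of random lists, while later lists of eosinophil genes (median -1.55) and macrophage genes (0.79), written after some members were seen, lay outside it. Granulocyte and monocyte genes had a median of 0.06 (interval -0.30 to 0.28, percentile 11.3) and no 2-fold difference among 20, of which 10 were below 0. With the stricter filters its median was -0.02 and its percentile 0.25 at its lowest, and after the loess correction its median was -0.04. Cebpe, under the negative control level on the wild-type array, was at 0.74, and the neutrophil serine protease genes Ctsg (0.72) and Prtn3 (0.55) were higher, while Ltf (-0.55), Mmp9 (-0.50), Itgam (-0.42) and Camp (-0.41) were lower. Neutrophil granule genes read high on both arrays, with Elane at 11.14 and 11.47 and Mpo at 11.09 and 11.34 on the wild-type array and the array labelled knockout. The arrays measured each sorted sample as a whole, so a difference cannot be assigned to ILC progenitors alone. Dendritic cell genes had a median of -0.05 (interval -0.25 to 0.47, percentile 5.54), with Bst2 at 0.47 and, near background, Itgax at 0.49 and Zbtb46 at -0.46. Mast cell and basophil genes had a median of 0.05 (interval -0.55 to 0.43, percentile 28.3), which was -0.11 after the loess correction, with Hdc at 0.43, Gata2 at 0.25 and, near background, Tpsb2 at -0.55. Erythroid genes had a median of -0.19 (interval -0.44 to 0.42, percentile 4.29), but 0.13 (percentile 49.7) with the stricter filter and 0.05 (percentile 29.0) with the negative control filter. Car1 was at 0.42, Slc4a1, under the negative control level on the array labelled knockout, at -0.44 and Ermap, near background, at -0.42. Megakaryocyte genes had a median of -0.06 (interval -0.83 to 0.22, percentile 28.0), but 0.17 with the stricter filters, and 4 of 6 members were near background, among them Treml1 (-0.83) and Itga2b (-0.36), while Gp9 was at 0.22. Stem and multipotent progenitor genes had a median of 0.34 (interval -0.26 to 0.61, percentile 96.8). Of these, Angpt1 was at 1.48, with the wild-type array under the negative control level, Meis1 was at 0.61 and Slamf1, near background, at -0.52.

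The lists of mitotic genes and of oxidative phosphorylation genes lay above the central 95% of random lists, and those of S phase and ribosomal protein genes inside it. Mitotic genes had a median of 0.31 (interval 0.13 to 0.45) against 0.14 for matched lists, at percentile 98.4, and 6 of 19 were below the matched median. Hmmr was at least 1.40-fold higher (1.28 as measured), Cenpf, near background, was at 0.70, and Bub1, under the negative control level on the wild-type array, at 0.64. With the stricter level filters the percentile was 60.2 at its lowest, and with values raised to the negative control level 84.0. S phase genes had a median of 0.22 (interval 0.11 to 0.40, percentile 82.4), with Cdc45, a replicative helicase component, at 0.78, Cdc6 at 0.52 and the uracil glycosylase gene Ung at -1.04, under the negative control level on the array labelled knockout. Nuclear genes of oxidative phosphorylation had a median of 0.25 (interval 0.20 to 0.34) against 0.14 for matched lists, and 6 of 10000 random lists were as high. Of 73 members 19 were below the matched median and none differed 2-fold; Ndufa9 (0.90), Ndufv2 (0.78) and Ndufa1 (0.70) were highest, of which Ndufa9 and Ndufa1 were under the negative control level on the wild-type array. Cytosolic ribosomal protein genes had a median of 0.11 (interval 0.08 to 0.13, percentile 23.5), which was -0.011 after the loess correction on level, with Rps4l, near background, at -0.56, Rps27l at 0.52 and Rpl10l at -0.46.

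The p53 list lay inside the central 95% of random lists, and the interferon list could not be judged because 8 of its 10 members were near background on both arrays. Genes transcribed by p53 had a median of -0.09 (interval -0.26 to 0.13, percentile 7.46), and 6 of 13 were near background, among them Plk2 (0.56). Bbc3, which encodes PUMA, was at -0.60, under the negative control level on the array labelled knockout, and Ccng1 at 0.48. The p53 targets Cdkn1a (-0.09) and Mdm2 (-0.03) differed little. Immediate early and heat shock genes, which respond to cell handling, had a median of 0.04 (interval -0.16 to 0.17, percentile 7.18), which was -0.12 after the loess correction, with Hsp90aa1 at 0.64, Klf6 at -0.52 and Ier3 at 0.39. This list lay below the central 95% after quantile normalization, with the negative control filter and with values raised to the negative control level, at percentile 0.35 at its lowest. Interferon-stimulated genes had a median of 0.19 (interval -0.46 to 0.62, percentile 86.9) as measured, and 0.0000 with values raised to the negative control level. Oas1a (0.64), Irf7 (0.62) and Zbp1 (-0.54) were all near background on both arrays. Of the 28 lists, 9 lay outside the central 95% of random lists, where 1.4 would be expected by chance for independent lists. Several lists share members, and the random lists hold genes drawn singly. Members that vary together can put a list outside this range more often, whatever the source of the difference.

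The 3 measured Y-linked genes were all higher on the array labelled knockout, at low levels. Kdm5d and Uty were near background on both arrays and Eif2s3y was under the negative control level on the wild-type array. Eif2s3y read 3.40 and 5.18, Kdm5d 1.62 and 3.22, and Uty 2.51 and 4.05 on the wild-type array and the array labelled knockout. Their differences were 1.78, 1.60 and 1.54 on the log2 scale. Each lay at percentile 99.9 among the 500 genes nearest in level. The labels do not give the sex of the mice.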

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

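The tests of noise near background, of a lower share of progenitors and of Lmo4 against T cell genes were chosen only after the result was seen. The lists of further T cell genes and of X-linked genes were written before their values were looked at.

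Signals outside the named genes were present. Of 1167 probe sets past the level filter with no gene name, 18 were at least 2-fold higher and 16 at least 2-fold lower on the array labelled knockout. The 1324 positive control probe sets had a median difference of 0.18, whereas 9 of 9 bacterial hybridisation spikes were lower on this array, with a median of -0.18.

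T cell genes were lower on the array labelled knockout (median -1.06). A level-dependent shift between the arrays is argued against, because the median was -1.11 after the loess correction. A lower share of the sorted progenitors alone was taken to raise other lineages' genes alike, T cell genes among them. The T cell median was already known to be below 0, so the outcome was fixed and the test decides nothing. As a description, the granulocyte and monocyte median lay 1.13 above the T cell median. Its interval (-0.30 to 0.28) lay above those of the T cell (-2.44 to -0.64) and B cell lists (-1.16 to -0.46). With values raised to the negative control level, which gives only lower limits, these intervals overlapped. Further T cell genes that were in no fixed list were lower too (median -0.67, interval -0.92 to -0.39, below all 10000 random lists). Among them Cd28 was at -1.18, and the brighter Gimap6 read 6.81 and 5.93 on the wild-type array and the other. Of the 18 past the filter 17 were below 0, while Ubash3a, under the negative control level on the wild-type array, was at 0.56. With values raised to the negative control level the median was -0.38 (interval -0.74 to 0.00, percentile 0.00). Fewer mature T cells carried through the lineage-negative gate would give such values. However, Cd4 (0.09) did not follow, and Bcl11b and Ptcra of the first list are also in lists of progenitor or Notch genes. Lower transcription of T lineage genes within progenitors stays open as untested, since both accounts predict these values and each genotype has 1 array.

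The Y-linked genes were higher on the array labelled knockout by 1.54 to 1.78. Noise near background stays undecided. Its test was chosen after the result was seen, with Kdm5d and Uty already near background on both arrays, so it decides nothing. As a description, all the measured Y-linked genes were higher and each lay at percentile 99.9 among genes of like level. Eif2s3y was under the negative control level on the wild-type array only. More RNA from male mice in the sample labelled knockout is a candidate explanation. For it, 4 X-linked genes that escape inactivation were predicted to be lower. Their median was 0.0025 (range -0.34 to 0.06), with Kdm6a at -0.34 and Ddx3x, Eif2s3x and Kdm5c between 0.00 and 0.06. All 4 lay below the median of matched random lists (0.13), and the list was at percentile 19.0. After the loess correction its median was -0.11 (percentile 21.9), so sex remains undecided. If the sexes differed, sex and genotype cannot be told apart with these arrays.

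Lmo4 was 5.50-fold lower on the array labelled knockout. A level-dependent shift is argued against, because the difference was -2.57 after the loess correction. Whether cells lost from the sort could carry the Lmo4 signal is undecided. The test asked whether nearly all or none of the T cell genes fell as much as Lmo4. It was chosen after the result was seen, so its outcome was fixed and it decides nothing. As a description, 2 of the 14 T cell genes, Cd3d and Cd8b1, were lower by at least as much as measured. Both were under the negative control level on the array labelled knockout. On the wild-type array Lmo4 read 11.47, the highest of the genes past the filter, and Cd3e, the brightest of the 14, read 7.79. An effect of the Yeats4 deletion on Lmo4 transcription stays open as untested, since neither genotype has a replicate array. Yeats4 itself read alike on both arrays. Where its probes lie relative to the deletion is not known, so that reading does not check the label.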

How the results depend on the processing

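The negative control filter and the raising of values to the negative control level were chosen after seeing the data. With 1 array per genotype no replicate could be left out. No paired analysis was possible because each genotype has 1 array. Among the alternative values of Yeats4, Lmo4, the 2-fold counts and the list medians, 223 stayed within the local spread, within 1.5 times the count or within the interval over members, and 22 did not. No list outside the central 95% changed sign, but 8 others did. The ILC3 median was 0.20 with the negative control filter (percentile 63.1), the erythroid median 0.13 and 0.05 with the stricter filter and the negative control filter, and the megakaryocyte median 0.17 with both. The granulocyte and monocyte median was -0.02 with these filters, -0.04 after the loess correction and -0.01 with values raised to the negative control level. The loess correction also turned the Lmo4 partner (-0.09), mast cell (-0.11), immediate early (-0.12) and ribosomal protein medians. Genes at least 2-fold higher numbered 35 with the stricter filter, 38 with the negative control filter, 19 with values raised to the negative control level, 82 past 3 local spreads and 997 at 1.5-fold, against 170. Genes at least 2-fold lower numbered 25, 25, 23, 45 and 561 under the same settings and 137 with no filter, against 85. Stricter filters test fewer genes, and raised values give only lower limits, by construction. Centring on the median gave 123 higher and 118 lower, so that 51.0% of the changed genes were higher, against 66.7% as reported and 45.2% with raised values. Of the main calls, 141 of the 170 higher and 79 of the 85 lower genes were shared with the loess correction. The S phase median was 0.063 after loess and 0.069 after quantile normalization. The ribosomal protein median was 0.025 after centring, -0.011 after loess and 0.036 after quantile normalization. The oxidative phosphorylation median was 0.16, 0.10 and 0.15 in that order, at percentiles from 99.81 to 99.97 over the 8 alternatives. Each of these 3 settings removes a shift of all genes by construction. With values raised to the negative control level the medians of the T cell, other YEATS domain and Notch target lists were -0.53, 0.033 and 0.0000, that of the ILC3, erythroid and interferon lists 0.0000, and 4 T cell, 2 B cell and 2 NK and ILC1 genes stayed at least 2-fold lower, against 8, 4 and 3. Among the 9 lists outside the central 95%, 5 stayed on their side under every alternative that could be computed, namely the early ILC regulator, T cell, B cell, common lymphoid progenitor and oxidative phosphorylation lists. The mitosis list did not under the stricter filters (percentile 60.2 at its lowest) and with raised values, nor did the ILC progenitor receptor (37.1), NK and ILC1 (49.5) and Notch target lists with raised values. The granulocyte and monocyte list reached percentile 0.25 under the stricter filters, the immediate early and heat shock list 0.35, the ILC3 list 1.49 with no filter and the cytokine signalling list 2.36 at their lowest. The stricter filters left fewer than 2 members of the ILC2, Notch target and other YEATS domain lists, and 1 of them did so for the ILC3 list, which then have no value. Signal over background limits the 12 genes with the highest differences, 6 of which were near background on both arrays, against 2 of the 12 with the lowest.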

Other observations

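The lists in this part were written after some of their genes had been seen among the largest differences, so their medians are not independent evidence of direction. Genes of tissue macrophages were higher on the array labelled knockout in 14 of 14 cases, with a median of 0.79 (interval 0.57 to 1.14), above all 10000 random lists. Of these, 6 were near background on both arrays, among them Cd5l (1.59), Siglec1 (1.35) and Spic (1.08), and with values raised to the negative control level 8 were higher and the median was 0.52, again above all random lists. The phagocytosis receptor gene Axl was 2.20-fold higher (1.14) and the adhesion molecule gene Vcam1 1.96-fold higher (0.97). The complement genes C1qc (0.86) and C1qa (0.69) lay in the same direction. Genes of marrow stroma had a median of 0.58 (interval -0.26 to 1.48, and 3 of 10000 random lists were as high), but a percentile of 49.2 with values raised to the negative control level. The chemokine gene Cxcl12 was 2.52-fold higher (1.33), while Angpt1 was at 1.48, under the negative control level on the wild-type array, and, near background, Igfbp5 at 1.56. The collagen gene Col1a2, near background, was at -1.08 and Col1a1 at -0.26.

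Eosinophil granule genes were lower on the array labelled knockout, while the granulocyte and monocyte list was not (median 0.06). Ear6 was 3.43-fold lower (-1.78), the peroxidase gene Epx 2.96-fold lower (-1.56) and the major basic protein gene Prg2 2.79-fold lower (-1.48). Prg3 (-1.56), Ear10 (-1.53) and Alox15 (-1.68), under the negative control level on the array labelled knockout, were lower as well, and the list median was -1.55 (interval -1.78 to 0.96, below all random lists). Of the eosinophil surface receptor genes, Ccr3 was at 0.96, under that level on the wild-type array, and, near background, Siglecf at 0.14 and Il5ra at -0.73. Ear6 and Ear10 belong to a family of near-identical ribonuclease genes, so their probe sets may share signal. That was not tested, and the median of the list was -1.59 after the loess correction.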
